A study of Ginkgo biloba and Gnetum montanum and Pinus tabuliformis with 10 samples.

How the data were processed

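Spatial transcriptomes of ovules were measured on 10 slides: stages 1, 2 and 3 of Ginkgo biloba, Gnetum montanum and Pinus tabuliformis and stage 1 of Cycas panzhihuaensis, with 1 slide per species and stage. Per the labels, tissue was frozen fresh and embedded in OCT, sections of 10 micrometres were taken, and libraries were made with BMK S1000 slides. The deposited matrices hold raw UMI counts per gene and spot, without normalization, as judged from whole numbers with different totals per spot. The other deposited tables hold spot names, spot positions in units that are not given, and gene IDs. The aligner, the genome builds, the annotations and any filtering of spots are not given in the sources used here. Names that differ from the IDs were deposited for 3713 genes of the Pinus stage 3 slide alone, and 3709 of these IDs are listed in all 3 Pinus slides, so names were matched by ID in that species only.

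The deposited files hold 85947 spots and 161245050 UMIs, and no spot was removed from the sums of a slide. Spots were joined into tissue pieces when they lay within 1.5 times the lattice spacing, and pieces of at least 50 spots were kept. Enclosed holes of up to 10 sites were filled. The outer zone of a piece held the spots at or below the 33rd percentile of distance to the nearest empty site outside it, and the inner zone those at or above the 67th percentile, so that zones rest on position alone. UMIs were summed per slide and zone. For Ginkgo, Gnetum and Pinus the 6 sums were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with the slide as a block, TMM factors and the filterByExpr filter, at a Benjamini-Hochberg adjusted p under 0.05 and with 2 residual degrees of freedom. The slides differ in stage, so the spread between slides holds any effect of stage on the zones. Fold changes are log2 values of outer minus inner spots. The stage 1 and 2 fit of Pinus used the same model. Cycas, with 1 slide, was described by log2 ratios of CPM, the counts scaled to a common total, for genes at 20 CPM or more, and by direction in 4 quadrants because the slide held 1 piece.

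Stages were compared without a test by log2 ratios of CPM summed over a slide, for genes with at least 100 UMIs in the higher slide, with exact 95% intervals from the counts. A ratio against 0 UMIs in a slide was computed against a floor of 3 UMIs and is given as a bound. Genes over 4-fold were counted, and the ranges over pieces were compared, with the share of non-overlap that random orders of the pieces give.

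Lists of genes and the rules for naming genes were fixed before the data were examined, as were the alternatives except those said to be added later. The lists that could be matched to deposited names were ovule and integument, meristem, terpene synthesis, auxin, flavonoid synthesis and lignin synthesis, tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated one, and abaxial polarity, cell division and vascular markers, which had fewer than 5 members. Family names stood in for single members (YABBY, WOX, KNAT, CUC and VND), which was decided on seeing the deposited names and not their values. The remaining lists fixed beforehand could not be matched with certainty and were left out. In the stage comparison, the median of a list was set against 10000 random lists of like mean CPM. These do not hold the correlation between members of a list, so percentiles can overstate a difference. Named genes were, per zone, the 10 with the largest fold change among those with adjusted p under 0.05, 1 direction in every slide and a mean of at least 20 CPM, and for stages the 5 per direction with the largest ratio and non-overlapping pieces. For lists, examples were those with the highest mean CPM, and examples beyond these were chosen after their values were seen. For IDs without names the first 2 per direction were taken.

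Moran's I was computed within each slide over neighbouring spots, on log1p of UMIs thinned to 250 per spot, for genes with at least 200 thinned UMIs. Spots with fewer than 250 UMIs were left out of it, which kept 2470 of 6761 spots at Pinus stage 3 and 4775 of 8155 at Pinus stage 2. Regions came from spots of at least 50 UMIs (4331 at Pinus stage 3), scaled to 10000 per spot and logged. The 2000 most variable genes, 30 principal components and 15 nearest spots were used, with Leiden clustering at resolution 1.0. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2, and plots were drawn with matplotlib 3.10.9.

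The zone test was tested on simulated data with 200 genes changed. It recovered 74% of the 2-fold changes in Ginkgo, 82% in Gnetum and 24% in Pinus, and 100, 100 and 97% of the 4-fold changes, with 3.33, 3.19 and 3.2% false calls. On simulated spots Moran's I had a median of 0.357 for patterned genes and a highest value of 0.0321 for the others. The clustering split 3 simulated regions into 8, with 93.8% of the spots in a region that matched, so the number of regions is not a number of tissues.

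Alternatives fixed beforehand for the zone test were DESeq2 1.42.0 size factors, DESeq2 itself with the slide as a block, no filter on low counts, no slide term, each slide left out, zones by the 25th and 75th percentiles, holes not filled, pieces of at least 100 spots, spots of at least 200 UMIs, zones thinned to 1 total and spots that touch the outside left out. For stages they were TMM factors, thinning to the smallest total and the mean over pieces. For patterning they were 500 and 125 UMIs per spot and Pearson residuals, and for regions resolutions 0.5 and 1.5. Added after seeing the data were zones without the border of the capture area as an edge, Pinus without 6150 IDs of doubtful comparability, Pinus stages 1 and 2 thinned to the totals of stage 3, DESeq2 on these 2 slides, the direction of stage 1 genes at matched depth, quadrants in Cycas, Pinus clustering without the named genes, and sets of genes whose names share a stem.

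Per spot, Pinus stage 3 was the shallowest slide, with a median of 93 UMIs, and in total Ginkgo stage 2, with 3372507 UMIs. Genes were not compared between species, because their IDs differ. No caller of mixed spots was used. Tissue types were not assigned, since the labels give none beyond ovules.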

Results

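Ovule tissue of 4 gymnosperm species was profiled by spatial transcriptomics on 10 slides. Ginkgo biloba, Gnetum montanum and the pine Pinus tabuliformis were each covered at stages 1, 2 and 3, and the cycad Cycas panzhihuaensis at stage 1. In this kind of assay a thin tissue section lies on a slide printed with barcoded spots, and every captured transcript is counted at its spot through a unique molecular identifier (UMI). Each species and stage had 1 slide, so no group had a replicate, and intervals quoted for a single slide cover counting error only. The slides carried several pieces of tissue each, except the Cycas slide with 1 piece, and the files do not say which piece is which ovule.

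The Ginkgo slides held 5780022, 3372507 and 11862197 UMIs at stages 1, 2 and 3, in 2378, 2007 and 8319 spots. The Gnetum slides held 11456607, 6102764 and 11345049 UMIs in 9633, 10020 and 9376 spots. The Pinus slides held 28267303, 14336463 and 3604141 UMIs in 11202, 8155 and 6761 spots. The Cycas slide was the deepest, with 65117997 UMIs in 18096 spots and a median of 2872 UMIs per spot. Its spots lay 4.783 units of the deposited coordinates apart, against 7.903 on the other slides, and the reason is not given. Values per spot or per lattice spacing may therefore not be on a like scale. Pinus stage 3 was the shallowest per spot, with a median of 93 UMIs, against 1051 and 511 at stages 1 and 2. In that slide 60.4% of the spots held fewer than 200 UMIs.

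The median of UMIs per spot differed between the surface and the interior of the tissue, and it did so in opposite directions in different species. By the median, outer spots of Pinus held more UMIs than inner spots, with log2 ratios of 3.44 at stage 1, 3.22 at stage 2 and 1.36 at stage 3. At stages 1 and 2 this held in all 4 and all 3 pieces, and at stage 3 in 8 of 10 pieces. Ginkgo outer spots were also higher, by 0.39, 1.02 and 0.69 on the log2 scale, in 7 of 10, 5 of 7 and 4 of 6 pieces. In Gnetum the ratio was -0.65 at stage 1 and -0.75 at stage 2, negative in all 3 pieces of each slide, and 0.40 at stage 3, positive in both pieces. The Cycas piece had a ratio of -0.87. Among spots of at least 200 UMIs the Pinus stage 3 ratio was -0.97, the opposite sign, and those of Gnetum stages 2 and 3 were 0.02 and 0.06. Those of Pinus stages 1 and 2 fell to 2.37 and 1.01. Without that filter, the summed UMIs of Pinus stage 3 were also lower in the outer than in the inner zone. There PtbHLH224, with 2 UMIs in each zone, had a log2 ratio of CPM of 0.34, outer over inner.

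**Figure D1:**
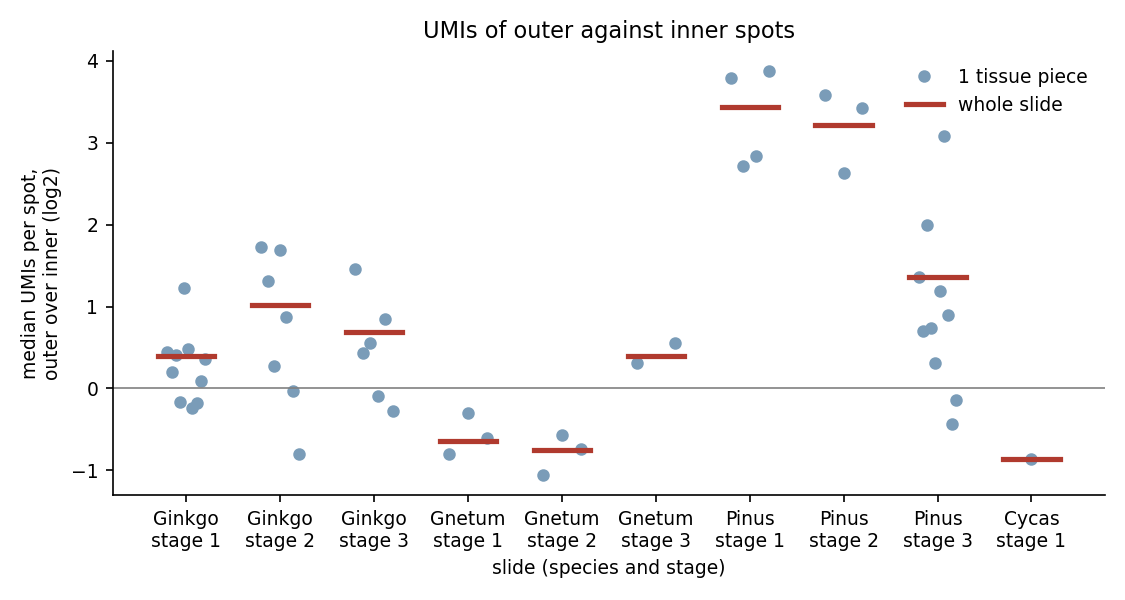
Median UMIs per spot in outer spots over inner spots (y axis, log2) for each of the 10 slides (x axis), with points for tissue pieces and red lines for whole slides. The Pinus slides of stages 1 and 2 sit highest, at 3.44 and 3.22, and Gnetum changes sign between stage 2 (-0.75) and stage 3 (0.40).

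The series title names the establishment of polarity, and the comparison of outer with inner spots addresses which genes differ between the surface and the interior of the ovule pieces. In Pinus at stages 1 and 2, single regulators such as PtYABBY1, PtLEAFY and PtWOX11 were higher in outer spots, and PtSUS7, PtNAC30 and PtSND3 were among the genes higher in inner spots. PtYABBY1, of the YABBY transcription factor family that marks the abaxial side of leaves in flowering plants, was higher in outer spots by 1.54 on the log2 scale (SE 0.22, adjusted p = 0.000716, the same direction in both slides). PtLEAFY, the pine relative of the floral regulator LEAFY, was higher in outer spots by 1.49 (SE 0.23, adjusted p = 0.00135, both slides), and the homeobox gene PtWOX11 by 1.56 (SE 0.25, adjusted p = 0.0021, both slides). In inner spots the sucrose synthase gene PtSUS7 was higher, at -2.95 (SE 0.35, adjusted p = 0.000163, both slides). The NAC genes PtNAC30 and PtSND3, the latter named after a regulator of secondary walls, stood at -2.72 (SE 0.30) and -2.21 (SE 0.24), also in both slides. The rule for naming these genes requires 1 direction in both slides.

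These values come from the edgeR fit of stages 1 and 2, which called 1185 of 21742 genes, 270 higher in outer and 915 higher in inner spots, with 1 residual degree of freedom. Of 1727 named genes tested, 45 were higher in outer and 88 in inner spots. The other named genes higher in outer spots were PtbHLH224 (1.84), PtbHLH144 (1.67), PtTCP5 (1.39), PtHB44 (1.34), PtARID4 (1.31), PtWOX13 (1.25) and PtTBL30 (1.21). The other named genes higher in inner spots were PtbHLH189 (-1.83), PtSDG77 (-1.82), PtMADS49 (-1.81), PtNAC82 (-1.76), PtWRKY18 (-1.75), PtNAC85 (-1.68) and PtGLK19 (-1.63). PtNAC82, PtWRKY18 and PtNAC85 rested on stage 1, where they stood at -2.78, -3.03 and -2.75, against -0.28, -0.34 and -0.59 at stage 2. DESeq2 called 486 genes from the same slides, 485 of them shared, and 14 of these 20 named genes; the 6 it did not call were PtARID4, PtWOX13, PtTBL30, PtNAC82, PtWRKY18 and PtNAC85.

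With the stage 3 slide included, edgeR called 0 of 18720 Pinus genes, where 1299 had an unadjusted p under 0.05 and DESeq2 called 21. Without the filter on low counts edgeR called 620, 198 higher in outer and 422 in inner spots. Leaving out each slide in turn was fixed beforehand, and the genes of the fit without stage 3 were described after this count was seen. At stage 3, 195 of the 497 called genes with at least 20 UMIs in that slide had the direction of the earlier stages, or 39.2% (exact 95% interval 34.9 to 43.7%). The interval treats genes as independent, which they are not. All 13859 tested genes with as many UMIs had 41.2%. Among the called genes the share was 55.0% for outer and 31.1% for inner genes, on either side of that value. The share of all tested genes was not split by direction, so whether outer or inner called genes stood apart was not tested. PtLEAFY is an example of a gene that turned, with 75 UMIs in outer and 203 in inner spots and a log2 ratio of -1.10 at stage 3. PtYABBY1 stood at 0.22 there, from 49 outer and 53 inner UMIs, and PtWOX11 at 0.48, from 31 and 28. Both ratios lie within counting error of no difference, so their direction at stage 3 is not settled.

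**Figure D2:**
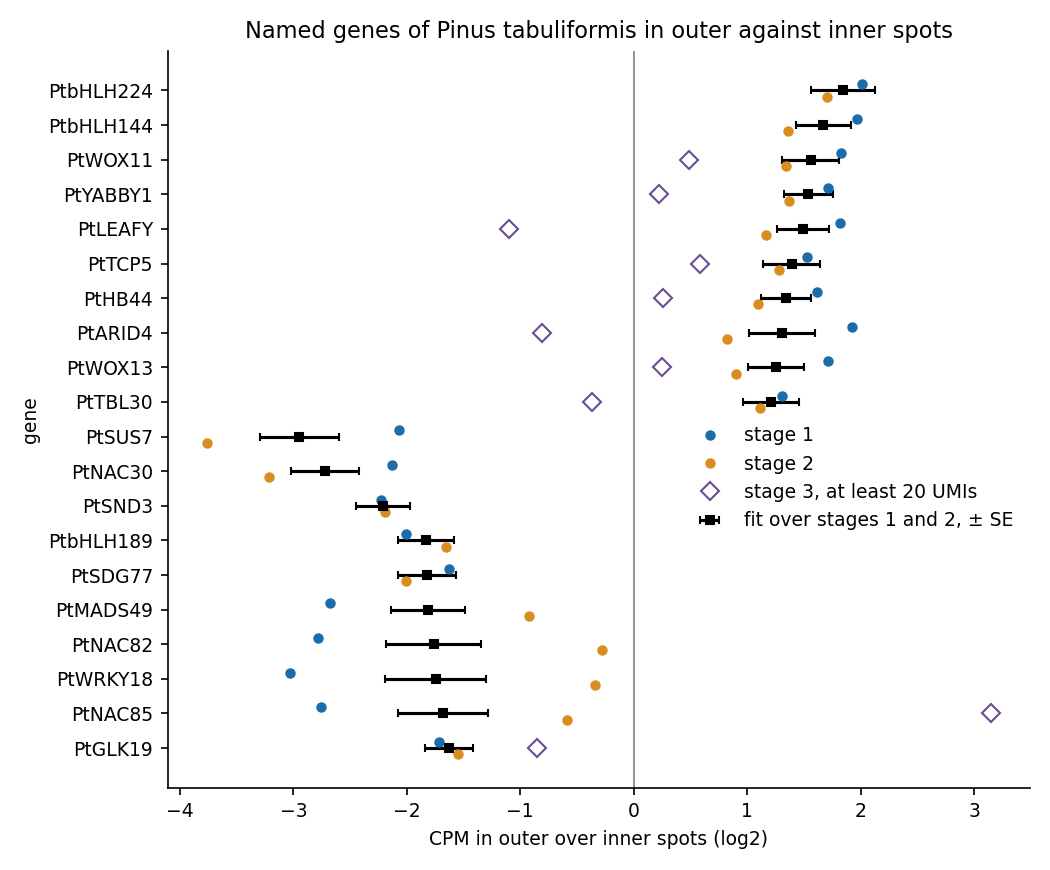
Log2 ratio of CPM in outer over inner spots (x axis) for the 20 named Pinus genes (y axis), where squares with bars give the fit over stages 1 and 2 with its SE, filled circles each of these slides, and open diamonds stage 3 for genes with at least 20 UMIs there. PtLEAFY stands at 1.49 in the fit and at -1.10 at stage 3.

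Of the 6 Pinus lists tested with camera, ovule and integument had the highest median towards outer spots. At stages 1 and 2, 5 of 12 measured members were higher in outer spots and 1 in inner spots over all genes, and 7 and 1 adjusted over the list alone. Their median was 1.01, with camera adjusted p = 4.22e-06 and adjusted p = 0.724 with an estimated correlation. PtANT, named after the integument growth regulator AINTEGUMENTA, stood at 1.09 (SE 0.21, adjusted p = 0.00651, both slides), and PtWOX12 at -2.28 (SE 0.49, adjusted p = 0.0138, both slides). PtNEEDLY, a conifer relative of LEAFY, had 0.52 (adjusted p = 0.205, both slides). Over all 3 slides this list had a median of 0.69, with 0 of 12 members called over all genes and 6 adjusted over the list alone, and adjusted p = 2.9e-08, or adjusted p = 0.206 with an estimated correlation. Of these 12 members 8 had WOX names, with a median of 0.46. WOX names also made up most of the list at stages 1 and 2, so it stands in large part for 1 gene family.

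Of the meristem list, PtCUC3 of the organ boundary genes was higher in outer spots at 1.19 (SE 0.30) and PtKNAT2 of the KNOX genes in inner spots at -1.33 (SE 0.25). These were the 2 calls among 9 measured members over all genes, against 5 outer and 3 inner adjusted over the list alone, with a median of 0.74 and adjusted p = 0.485. Of 3 YABBY genes of the abaxial polarity list, PtYABBY1 was called over all genes, PtYABBY4 had 1.19 (adjusted p = 0.0506, both slides) and PtYABBY2 -0.86 (adjusted p = 0.204), resting on stage 2 with next to no difference at stage 1. Lignin synthesis had 3 of 26 members higher in inner spots, 7 adjusted over the list alone: PtCCR1 at -1.02, Pt4CL1 at -1.39 and PtCOMT1 at -2.02, with a list median of -0.27 and adjusted p = 0.0744. Of the vascular markers, PtVND1 was higher in inner spots at -1.73 and PtVND2 stood at -1.27 (adjusted p = 0.0875, both slides). Terpene synthesis had 1 of 25 members called, PtHMGR9 at 1.06, and a median of 0.06 (adjusted p = 0.595). Auxin genes had 0 of 25 members called, a median of 0.18 and adjusted p = 0.082, and flavonoid synthesis 0 of 7, a median of 0.14 and adjusted p = 0.595. The single cell division name, PtH2A, stood at 0.02.

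Over all 3 Pinus slides the meristem, terpene and auxin lists also leaned to outer spots, with medians of 0.38, 0.37 and 0.24. Their camera adjusted p were 0.00149, 0.00651 and 0.0279. With an estimated correlation these became adjusted p = 0.206, adjusted p = 0.376 and adjusted p = 0.376, so none of the 4 calls was kept. For the meristem list correlation does not account for this, since its estimate was -0.002, below the preset 0.01. The estimates for the ovule, terpene and auxin lists were 0.1525, 0.1522 and 0.0799, above the preset, so correlation may bear on these. Camera with an estimated correlation also takes the 2 residual degrees of freedom, too few to decide on a list. The flavonoid and lignin lists had adjusted p = 0.624 and adjusted p = 0.904, and for lignin the median of -0.03 and the outer direction of camera differed in sign.

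In Gnetum, edgeR called 334 of 12903 genes, 166 higher in outer and 168 in inner spots, and 331 of these had the same direction in all 3 slides. The files do not pair the IDs of Gnetum, Ginkgo or Cycas with names. TnS000982175g01 was higher in outer spots by 3.67 on the log2 scale (SE 0.46, adjusted p = 0.016) and TnS000535969g01 by 3.35 (SE 0.40, adjusted p = 0.0145). TnS000456907g09 and TnS000946403g06 were higher in inner spots, at -1.95 (SE 0.22, adjusted p = 0.0132) and -1.94 (SE 0.17, adjusted p = 0.0086). All 4 had the same direction in all 3 slides, which the rule for naming genes requires. The log2 ratios of the single slides correlated at rho 0.21 for stages 1 and 2, 0.16 for stages 1 and 3 and 0.40 for stages 2 and 3. In the same order they were 0.08, 0.14 and 0.17 in Ginkgo and 0.38, -0.25 and -0.04 in Pinus, across genes, and genes are not independent replicates. The count was 963 without stage 1 (625 outer, 338 inner), 115 without stage 2, 112 with spots touching the outside left out, 836 without the filter on low counts and 0 without the slide term. DESeq2 called 299 outer and 180 inner genes, and with holes not filled edgeR called 214 and 134, so the split of directions depended on the setting.

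In Ginkgo, edgeR called 137 of 11806 genes, 88 higher in outer and 49 in inner spots, and 92 of them had the same direction in all 3 slides. Gb_39304 was higher in outer spots by 2.88 on the log2 scale (SE 0.21, adjusted p = 0.00276) and Gb_25895 by 2.60 (SE 0.31, adjusted p = 0.00676). Gb_26541 and Gb_22835 were higher in inner spots, at -3.10 (SE 0.30, adjusted p = 0.00514) and -2.89 (SE 0.28, adjusted p = 0.00514). By the same rule these 4 genes had the same direction in all 3 slides. For Gb_22835, however, stage 1 rests on 5 outer and 4 inner UMIs and for Gb_26541 stage 2 on 2 and 3, within counting error. The count was 90 without stage 1, 354 without stage 2, 58 without stage 3, 37 with spots touching the outside left out, 230 with zones thinned to 1 total, 691 without the filter on low counts and 0 without the slide term.

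By Moran's I, Cycas had the strongest single pattern, a small interior patch rich in a few transcripts, on a slide with a closer spot lattice. CYCAS_000813 took at least 2% of the UMIs in 439 spots, 2.43% of the slide, and these spots held 92.0% of its UMIs. The gene made up 11.4% of all UMIs there, and the median distance of these spots from the tissue edge was 52.0 lattice spacings, where the deepest spot of the slide lay at 56.8. CYCAS_000747 had the same position, with 87.6% of its UMIs in 335 spots. Between zones, 1133 of 7858 genes at 20 CPM (counts scaled to a common total) or more differed over 2-fold, 470 higher in outer and 663 in inner spots, and 433 and 469 of these had the same direction in all 4 quadrants of the piece. CYCAS_032794 and CYCAS_009953 were the highest in outer spots, with log2 ratios of 7.12 (95% interval 6.19 to 8.25) and 6.98 (6.38 to 7.66). CYCAS_000747 had -7.60 (-7.79 to -7.41) and CYCAS_023966 -7.58 (-9.45 to -6.21), although the first of these was at 0.09 in 1 quadrant. With 1 slide no test was made.

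**Figure D3:**
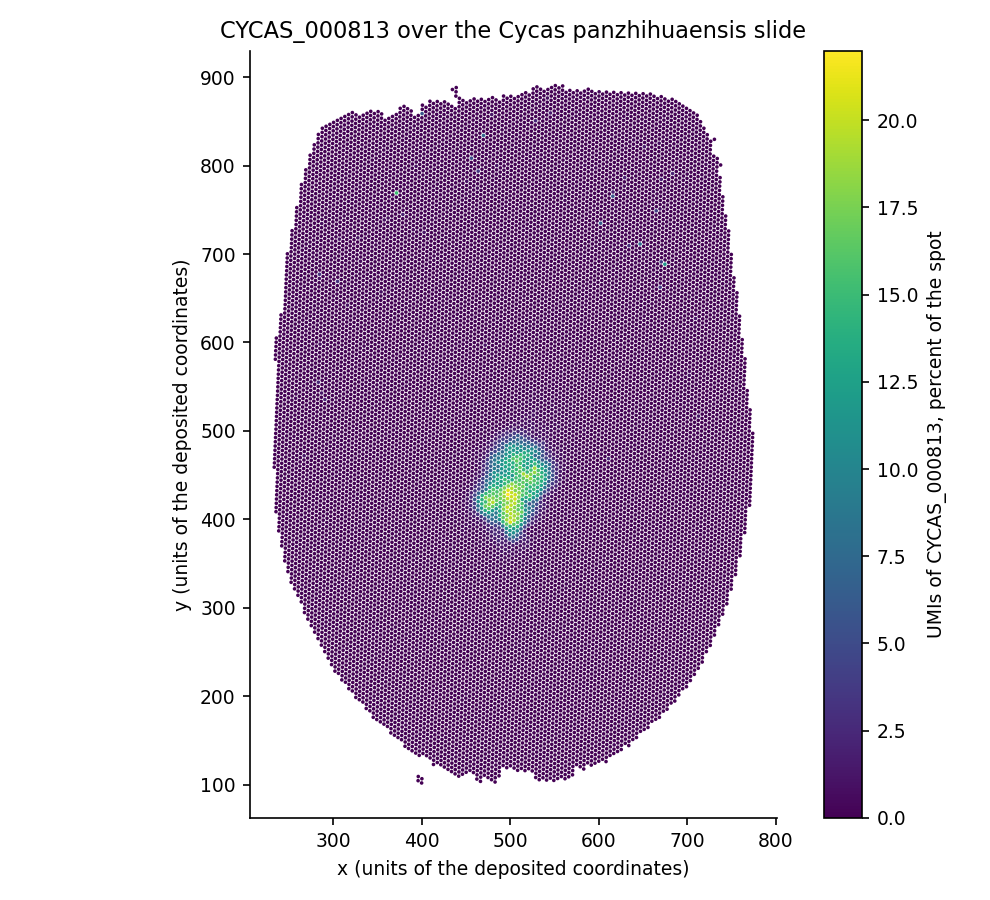
Share of the UMIs of each spot that came from CYCAS_000813 (color, percent) over the Cycas slide, with x and y in the units of the deposited coordinates. Of the 439 spots with at least 2%, 418 join into 1 patch inside the tissue.

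The stage comparison addresses which genes differ along ovule development. In the Pinus stage 2 slide, 4 of 7 flavonoid genes and 9 of 21 lignin genes were over 2-fold higher than at stage 1, with no test possible between single slides. The 7 flavonoid genes had a median log2 ratio of 1.34, with 0 of them over 2-fold lower, at percentile 99.8 of random lists of like abundance. In the zone test over 3 slides, 6 of the 7 measured genes of this list were F3H names, and the estimated correlation within the list was 0.725. The random lists do not hold such a correlation, so the percentile can overstate how unusual the list is. PtLDOX, the enzyme of anthocyanidin formation, stood at 2.09 and the more abundant flavanone hydroxylase genes PtF3H3 and PtF3H6 at 1.92 and 0.78. Of the lignin genes 2 were over 2-fold lower, and the list had a median of 0.64 at percentile 99.91, and its 4 most abundant members were PtCOMT2 (-1.49), PtCCoAOMT1 (0.44), PtCAD4 (2.04) and PtCAD1 (0.08). The 22 terpene genes went both ways, 8 higher and 6 lower, with a median of 0.48 at percentile 99.93. Auxin, ovule and meristem lists had medians of 0.12, -0.07 and -0.30, the YABBY genes 0.14, PtH2A -0.14 and the VND genes 0.74.

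Between Pinus stages 1 and 3, all 3 YABBY genes were over 2-fold lower at stage 3, with PtYABBY1 at -1.89 and PtYABBY2 at -2.45. The meristem list had a median of -1.24, at percentile 0.96, with 5 of 9 genes over 2-fold lower, and 1 higher, PtCUC7 at 1.77, and its most abundant members were PtKNAT5 (0.25), PtKNAT3 (-3.40) and PtCUC2 (0.36). Auxin genes had a median of -0.74, at percentile 0.25, with 7 of 21 lower and 2 higher, and its 4 most abundant members were PtARF11 (-0.45), PtARF9 (-0.20), PtARF10 (-0.74) and the auxin carrier gene PtPIN2 (-3.55). PtANT was at -3.07, while PtWUS was at 3.78, PtLEAFY at -0.02 and the ovule list at a median of -0.36, with 2 of 12 lower and 1 higher. Terpene genes had a median of 0.50, 9 higher and 7 lower of 22, at percentile 99.5, and the 4 most abundant pathway genes were PtHMGR9 (4.70), PtDXS1 (-2.72), PtHMGR15 (-0.61) and PtDXS2 (4.25). Lignin genes had 0.41 at percentile 92.97, or 0.24 without the IDs of doubtful comparability described below, flavonoid genes -0.99 at percentile 40.0 and PtH2A 0.74, and both VND genes were over 2-fold lower.

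**Figure D4:**
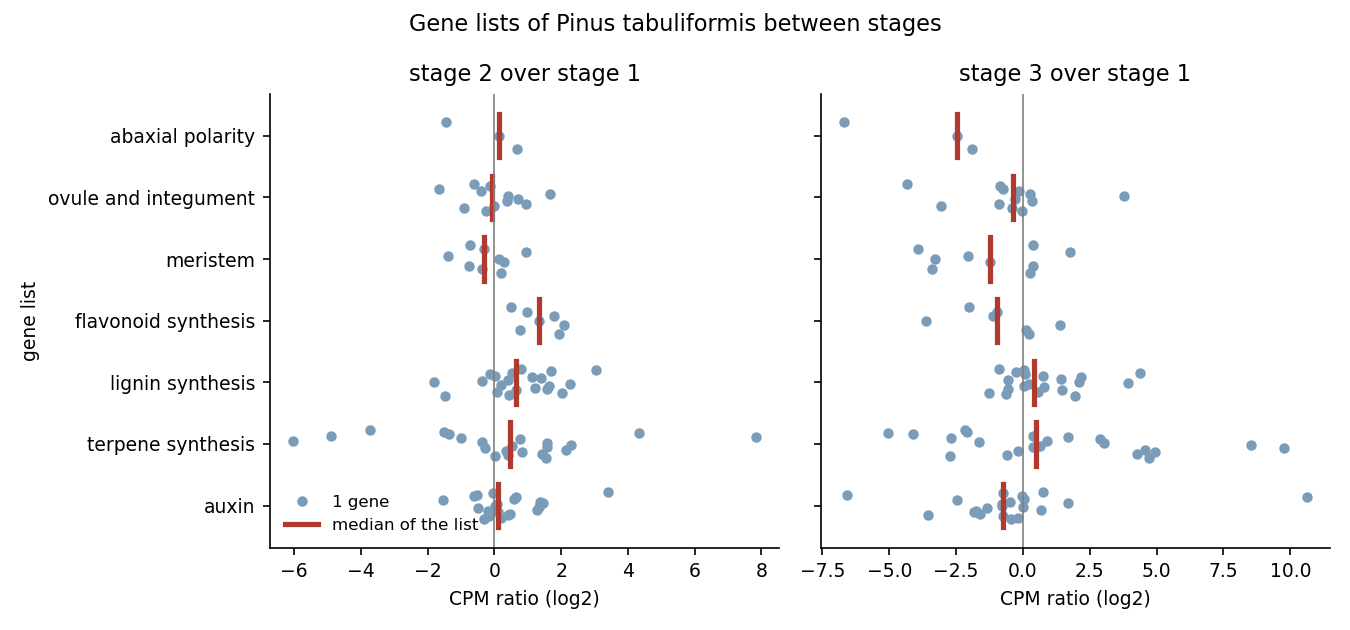
Log2 ratio of CPM between Pinus stages (x axis) for the members of 7 gene lists (y axis), with a point per gene, at its bound where 1 slide had 0 UMIs, and a red line at the median. Flavonoid synthesis has its median at 1.34 for stage 2 over stage 1 and at -0.99 for stage 3 over stage 1.

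The named Pinus genes highest at stage 3 against stage 1 were PtERF55 (at least 10.69 on the log2 scale), PtIAA15 (10.61, 95% interval 8.12 to 15.92, from 1 UMI at stage 1), PtUXS2 (at least 10.35), PtbHLH121 (10.09, 7.59 to 15.41, from 1 UMI) and PtHMGR12 (9.78, 8.22 to 12.06, from 3 UMIs). The lowest were PtMADS53 (-8.995, -12.04 to -7.14, with 2 UMIs at stage 3), PtMADS39 (-7.57, -9.85 to -6.02, with 3 UMIs), PtACO5 (-7.51, -10.55 to -5.65, with 2 UMIs), PtPOB1 (at most -7.42) and PtbHLH186 (at most -7.19). Bounds set a count of 0 to a floor of 3 UMIs. PtERF55, PtIAA15 and PtUXS2 have IDs of the Pt0G series, and PtPOB1 and PtbHLH186 have IDs at the ends of series that hold 0 UMIs at stage 3.

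In the Pinus stage 3 slide 1893 IDs at the ends of 4 ID series had 0 UMIs, although they held 1.90% of all UMIs at stage 1 and 1.85% at stage 2. The Pt0G series held 0.802% of the UMIs at stage 1 and 3.51% at stage 3. Of 18926 Pinus genes, 3727 differed over 4-fold between stages 1 and 3, 974 higher at stage 3 and 2753 lower. Without the 6150 IDs of these runs and of Pt0G the count was 3059 of 18121, 780 higher and 2279 lower. Without them the next named genes by the same rule were PtDAL22 (8.31), PtGGPPS5 (5.21) and PtbHLH177 (4.86), higher, and PtZFP54 (-7.08) and PtHCT2 (-6.90, -12.21 to -4.42, with 1 UMI), lower. Between stages 1 and 2 the count was 1487 of 19059, 640 higher at stage 2 and 847 lower.

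**Figure D5:**
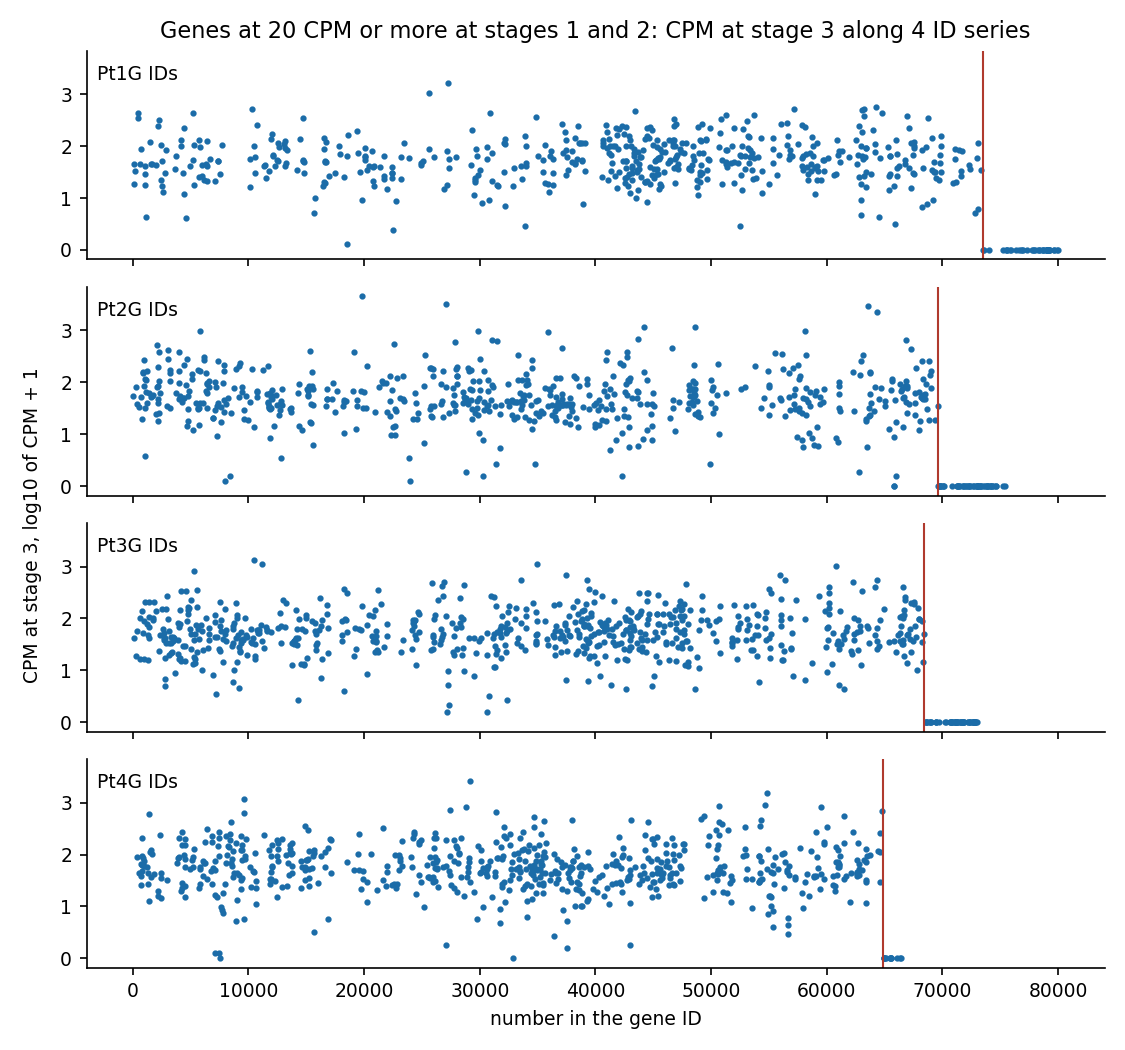
CPM at stage 3 (y axis, log10 of the value plus 1) of Pinus genes that have 20 or more at stages 1 and 2, along the number in the gene ID (x axis), for 4 ID series. Red lines mark the last ID with a UMI at stage 3, and to their right all genes lie at 0.

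In Ginkgo the stage 1 slide stood apart from the other two. There 3056 of 10307 genes differed over 4-fold between stages 1 and 3, 2260 higher at stage 3 and 796 higher at stage 1, and the slides correlated at rho 0.51. Stages 1 and 2 correlated at rho 0.45 and stages 2 and 3 at rho 0.74. At 20 CPM or more in both later slides, 73 genes had 0 UMIs at stage 1, and the cause was not tested. In Gnetum the count was 373 of 10970, 123 higher at stage 3 and 250 at stage 1, with rho 0.91. These correlations are across genes, and genes are not independent replicates. The Ginkgo genes with the largest ratios were Gb_39935 (13.33 on the log2 scale, 10.85 to 18.63, from 1 to 21054 UMIs) and Gb_29026 (12.52, 10.04 to 17.82, from 1 to 12037 UMIs). In the other direction they were Gb_24511 (-15.46, -20.76 to -12.98, with 1 UMI at stage 3) and Gb_07624 (-14.75, -16.63 to -13.40, from 53817 to 4 UMIs). In Gnetum TnS000178043g03 was at least 9.62 higher on the log2 scale at stage 3 (from 0 to 2342 UMIs) and TnS000058005g04 stood at 9.46 (6.97 to 14.76, from 1 UMI). TnS000753737g01 had -9.45 (-14.76 to -6.97) and TnS000664901g03 -8.79 (-14.09 to -6.30), each with 1 UMI at stage 3.

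Between stages 1 and 2, Ginkgo had 1572 of 6781 genes over 4-fold apart and Gnetum 116 of 10583. The ranges of the tissue pieces at stages 1 and 3 did not overlap for 5204 Ginkgo genes, or 50.5%, where chance gives 0.025%. For Pinus this held for 4295 genes, or 22.7%, where chance gives 0.2%, and for Gnetum for 5877 genes, or 53.6%, where chance gives 20%. Pieces of 1 slide are not replicates. With TMM scaling the median log2 ratio over all genes moved from 0.51 to 0.30 for Ginkgo and from -0.05 to -0.25 for Pinus at stage 3 over stage 1, and from 0.10 to -0.07 for Gnetum at stage 2 over stage 1. No median of a Pinus list changed sign with it.

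Spatial patterning asks which genes vary smoothly over the tissue. On thinned counts most genes had low values: the median Moran's I per slide lay between 0.00414 and 0.0208, and 716 of 16298 gene and slide pairs, or 4.39%, were over 0.1. With Pearson residuals of the full counts 4240 of the same pairs, or 26.0%, were over 0.1. The highest values were those of CYCAS_000813 (0.976) and CYCAS_000747 (0.969) in the interior patch of Cycas. Spots of that slide lay closer together than those of the others, so its values may not compare directly. Gb_25968 was among the 2 highest at Ginkgo stages 2 and 3 (0.615 and 0.515), and TnS000674083g01 led at Gnetum stages 1 and 2 (0.448 and 0.516). PtJG34130 led at Pinus stage 1 (0.658) and Pt4G30500 at Pinus stage 3 (0.588). Among Pinus genes with a name, chosen after their values were seen, PtNAC85 was the highest at stage 1 (0.242) and stage 2 (0.117), and PtDXS2, of the plastid terpene precursor pathway, at stage 3 (0.178), where 2470 of 6761 spots were deep enough to be used. Genes with high values recurred between Gnetum slides, where 78 of the top 101 genes of stages 1 and 2 were shared and chance gives 5.03. For the same stages 25 of the top 48 were shared in Pinus, where chance gives 2.4, and 1 of the top 7 in Ginkgo, where chance gives 0.31. The other pairs of Ginkgo slides shared more. Stages 1 and 3 shared 11 of the top 15, where chance gives 0.71, and stages 2 and 3 shared 7 of the top 14, where chance gives 0.70. Chance here takes all genes as equally likely to rank high, and abundance was not matched. Where in the tissue the shared genes were high was not compared. Values correlated between slides of a species at rho 0.43 to 0.50 in Gnetum, 0.46 to 0.55 in Pinus and 0.28 to 0.66 in Ginkgo, across genes, which are not independent replicates.

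Clustering of spots by expression gave regions in which neighbouring spots were together more often than after shuffling. The slides split into 8, 8 and 17 regions for Ginkgo, 17, 16 and 16 for Gnetum, 24, 18 and 10 for Pinus and 24 for Cycas. Neighbouring spots shared a region in 47.5 to 71.7% of pairs, against 5.25 to 17.4% after shuffling. Some regions were less compact, such as region 17 of Ginkgo stage 3 with 9.09% and region 8 of Pinus stage 2 with 27.5%. Regions also differed in depth, with medians from 89 to 7645 UMIs per spot at Pinus stage 1 and from 83 to 3048 at Ginkgo stage 3, and the part of depth in them was not separated. In Cycas, region 23 with 316 spots held 84.6% of the UMIs of CYCAS_000813.

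Pinus had a region rich in terpene genes at every stage when spots were clustered without the named genes, an alternative added after the data were seen. At stage 2 the terpene list was highest in region 12, with 204 spots, at 4.94 times the level of the other spots, with 18 of 25 members higher and the same direction in 3 of 3 pieces. PtDXS2 was 45.8-fold higher there, the terpene synthase gene PtTPS_mo6 34.8-fold and PtTPS_di11 19.8-fold. At stage 3 the list was highest in region 8, with 167 spots, 84.4% of them outer, at 4.79 times the level of the other spots, in 4 of 4 pieces. Named genes higher in region 8, ranked over all names and not the list alone, included PtDXS2 (18.4-fold), PtHDS (6.46-fold) and PtHDR1 (5.26-fold). The same region was also the highest for the meristem (2.34 times) and lignin (1.95 times) lists, and region 12 of stage 2 for the meristem list (1.46 times). At stage 1 the terpene list was highest in region 24, with 71 spots of 1 piece, at 4.15 times. Named genes higher there, ranked over all names, included PtTPS_mo8 (60.4-fold) and PtHDR2 (12.7-fold). The ovule and integument list was highest in region 17 at stage 1 (1.90 times, 82.2% outer spots), region 14 at stage 2 (2.46 times) and region 2 at stage 3 (1.65 times, 78.7% outer spots). These regions were picked as the highest of 24, 19 and 9, so no test was made of them.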

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

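Tests of the order of the Pinus IDs, of the UMIs expected at stage 3, of the runs of genes at 0, of the Pt0G share and of the stage 1 genes at matched depth were chosen after the result was seen, and the fits with thinned slides and without the capture border were added after the data were seen.

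Outer spots of Gnetum held fewer UMIs than inner spots in every piece at stages 1 and 2 and more in both pieces at stage 3, which is why this result is listed here. The log2 ratio of stage 3 was 1.04 above that of stage 1 and 1.15 above that of stage 2, and this difference was not tested; among spots of at least 200 UMIs the ratios were -0.43, 0.02 and 0.06, a filter on the quantity compared that decides nothing. The border of the capture area taken as a tissue edge is argued against, since the ratio of stage 3 was 0.33 with the border not counted and those of stages 1 and 2 were -0.74 and -0.76. Stage and section quality stay open, as each stage had 1 slide and pieces are not replicates.

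The Pinus stage 3 list of IDs held 91 IDs that the other Pinus slides do not list, and 40 of them carried 4209 UMIs, or 0.117% of the slide, a signal outside the comparisons. A larger pattern concerns IDs that all 3 slides list: of 8060 genes at 20 CPM or more at stages 1 and 2, 168 had 0 UMIs at stage 3, and 160 of these, or 95.2%, lie beyond the last ID of their series with a UMI there. Lower depth is argued against, since a median of 143.8 UMIs was expected for them, and so is stage of development as the whole cause, since they form end runs of at least 13 genes while the longest other run has 2. In the other direction, 129 of the 147 genes at 20 CPM or more at stage 3 alone, or 87.8%, belong to Pt0G, a series with 3.54% of the genes at that level. A candidate explanation for both is that stage 3 was counted against another gene list or reference than stages 1 and 2, a hypothesis found and tested on the same data.

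Zone calls in Pinus appeared without the stage 3 slide, 1185 against 0 with it. Lower depth as the whole cause is argued against by genes over 2-fold apart at stage 1: with stage 2 thinned to the totals of stage 3, 80.3% of 824 outer and 79.2% of 341 inner genes had the direction of stage 1, against 32.0% and 26.7% at stage 3, a mean share lower by 50.4 points. Depth as a part of the cause cannot be told apart, because thinning stages 1 and 2 to the totals of stage 3 left 490 calls, 41.4% of the number without thinning, between the outcomes stated beforehand. Of the called genes with 20 UMIs at stage 3, 39.2% had the same direction there (55.0% of outer and 31.1% of inner genes). Zone differences at stage 3 in other genes or the other way could give such a share. However, all 13859 genes tested had 41.2%, a share that was not split by direction. Stage and the quality of this slide stay open.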

How the results depend on the processing

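The counts without the capture border, those without the doubtful Pinus IDs and both alternatives for Pinus stages 1 and 2 were chosen after the result was seen. No list call and no named gene value reversed under another setting. The split of the Gnetum calls did move, from 166 outer and 168 inner genes to 299 and 180 with DESeq2 and to 214 and 134 with holes not filled. The depth ratio of outer over inner spots turned in Pinus stage 3 (1.36 to -0.97) and Gnetum stage 2 (-0.75 to 0.02) among spots of at least 200 UMIs. Without a filter on low counts the zone test called 691 genes in Ginkgo, 836 in Gnetum and 620 in Pinus, and the cause was not tested. Without the slide term it called 0 in Ginkgo and 0 in Gnetum, where differences between slides enter the spread. With touching spots left out it called 37, 112 and 3, and with zones thinned to 1 total 230 in Ginkgo, and the cause was not tested. Leaving out 1 slide gave 58 to 354 genes in Ginkgo (354 without stage 2), 115 to 963 in Gnetum (963 without stage 1) and 0 to 1185 in Pinus (1185 without stage 3). DESeq2 called 21 in Pinus, and for Pinus stages 1 and 2 it called 486 and the thinned fit 490, against 1185. With an estimated correlation the lists had camera adjusted p = 0.2056 (ovule and integument), 0.2056 (meristem), 0.3762 (terpene) and 0.3762 (auxin). Camera then takes the 2 residual degrees of freedom, so this setting cannot decide on the lists. Genes over 0.1 in Moran's I numbered 716 of 16298 gene and slide pairs (4.39%), against 4240 of the same pairs (26.0%) with Pearson residuals. With 500 UMIs per spot they were 1527 of 28025 (5.45%) and with 125 they were 333 of 7482 (4.45%). The number of pairs measured changed with these settings, so the shares do not show that values were stable. Values of single genes moved with the UMIs per spot, not all in 1 direction at 500. At Pinus stage 1 PtNAC85 went from 0.242 to 0.4115 with 500 and 0.1296 with 125, and PtDXS1 from 0.048 to 0.040 with 500. The cause of the rise with residuals was not tested. Of 111 values of named zone genes of Ginkgo and Gnetum 103 stayed past the threshold, and the 8 others were those without the slide term. Of 51 values of named stage and Cycas genes 49 stayed within their counting interval, and 31 more had no finite value because a count was 0. Counts over 4-fold between stages and the Cycas count stayed within 1.5 times their value under every setting tried. The number of regions summed over slides went from 158 to 107 at resolution 0.5 and 206 at 1.5, and single slides moved more, such as Gnetum stage 2 from 16 to 9 at 0.5.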

Other observations

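The sets of genes whose names share a stem, the members named from them and the other splits of the sums were chosen after the result was seen.

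Most genes with names in MADS, a family that in seed plants includes regulators of reproductive organ identity, were lower at Pinus stage 3 than at stage 1. Of 27 such genes, 22 were over 2-fold lower and 1 higher, with a median log2 ratio of -3.16 at percentile 0.0 of 10000 random lists of like abundance. None of the 27 is among the IDs of doubtful comparability, but whether another reference at stage 3 also affected other IDs was not tested. The genes with names in DAL, which are MADS-box genes too, went both ways, with 6 of 12 lower and 2 higher, PtDAL22 at 8.31 among them. PtMADS3 stood at -4.31 (95% interval -4.89 to -3.79) and PtMADS38 at -2.80 (-3.21 to -2.42). Genes with names in LOB, of the lateral organ boundaries family, were 11 lower and 4 higher of 18, with a median of -2.97 at percentile 0.0. PtLOB40 had -5.15 (-5.99 to -4.42) and PtLOB83 -3.77 (-4.16 to -3.40), while PtLOB89 had 3.17 (2.94 to 3.40). Names in TIFY, a family that includes repressors of jasmonate signalling, had 10 higher and 5 lower of 18, with a median of 1.21, and its 4 most abundant members were PtTIFY8 (-0.22), PtTIFY37 (1.80), PtTIFY60 (1.25) and PtTIFY5 (2.03).

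At stage 2 against stage 1, genes with names in WRKY had 10 of 23 over 2-fold higher and 0 lower, with a median of 0.57 at percentile 99.95, although the 2 most abundant members, PtWRKY56 (-0.82) and PtWRKY50 (-0.36), were lower and the next, PtWRKY52, stood at 1.86 (1.76 to 1.96). Names in DREB had 14 higher and 2 lower of 37, with a median of 0.69, and of its 4 most abundant members PtDREB1 had 1.26 (1.21 to 1.31), PtDREB91 0.80, PtDREB89 -0.44 and PtDREB79 -1.0. Names in mTERF, a family that acts in organelles, had 24 of 80 lower and 2 higher, with a median of -0.65 at percentile 0.06, and PtmTERF17, the most abundant, had -0.64 and PtmTERF25 -1.32 (-1.48 to -1.16). Each stage had 1 slide, so these are differences between slides.

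Between zones of the 3 Pinus slides, 39 genes with names in DREB had a median of -0.60, towards inner spots, with camera adjusted p = 2.6e-10, and adjusted p = 0.897 with an estimated correlation. Names in ACO had a median of -1.14 over 6 genes, with 3 higher in inner spots adjusted over the list alone and adjusted p = 0.897 with an estimated correlation. No gene of either set was called over all genes.

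The 6 sums of a species make 10 splits into equal groups, too few for a share under 0.05. In Ginkgo the real split called 137 genes and the highest other 216, and 3 of the 10 splits called as many as the real one. The 216 came from 2 splits that part the zones of 1 slide alone, and the 3 other splits that part the zones of all 3 slides, as the real one does, called 0 with edgeR, where 143 to 592 genes had an unadjusted p under 0.05. In Gnetum the real split called 334 and the highest other 0, so that 1 of the 10 splits reached it. In Pinus the real split called 0 and the highest other 132, and that 10 of the 10 splits called as many is fixed by the real count of 0 and says nothing. The split with 132 calls is the one with the zones of the stage 3 slide swapped, and it points to a structure of the samples, in which the log2 ratios of stage 3 correlate at rho -0.25 with stage 1 and -0.04 with stage 2, across genes, which are not independent replicates.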
